A study of Homo sapiens with 66 samples.

How the data were processed

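Total RNA had been extracted with Trizol from peripheral blood neutrophils and labelled with biotin for Affymetrix expression arrays, per the labels' protocols. The 66 samples were grouped by the disease status in the labels into 11 Normal, 13 PV, 24 ET and 18 AMM. RMA and Partek are named in the submitters' processing notes, and their versions are not given in the sources used here. The labels give 1 treatment text to all 66 samples. It describes patients with de novo disease, which cannot hold for Normal, so it was not used and whether samples came from treated or untreated people is taken as unknown.

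The deposited values were log2 values of 22406 probe sets, with 1 column for each sample, and all columns were used. They lay between 1.94 and 3.94, with a median of 2.36, where RMA gives values on a log2 scale several times as wide. Raising 2 to each deposited value gave 3.83 to 15.37 with a median of 5.12, the range usual for RMA. The reading was checked on 1648 pairs of probe sets of the same gene that correlated above 0.85 over arrays: the slope of their log2 SD ratio on their log2 level ratio was -0.80 for the deposited values and 0.13 after powering, where 0 means a spread that does not depend on the level. The powered values were used as log2 expression in every test. That a second logarithm had been taken is inferred from the values and is not given in the sources used here; the design fixed earlier had assumed plain log2 values. No background correction or normalization was added, and the table held 0 Affymetrix control probe sets, so signal over background and RNA degradation were not assessed.

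Genes were named from the platform annotation supplied with the table, in which 19415 probe sets had 1 gene, 125 had several and 2866 were unnamed here. Symbols were checked by gene identifier against RefSeq names of the assembly GRCh38.p14, and 0 were updated; no coordinates were used. Probe sets with several genes were left out. For the 4496 genes with 2 or more probe sets, the probe set with the highest mean over all arrays stood for the gene. XIST and Y-linked genes, 31 in all, were left out, which left 11909 genes.

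Group means were fitted to all 66 arrays at once in a one-way design, and contrasts were tested with limma 3.58.1 (lmFit and eBayes, two-sided, in R 4.3.3), since the design text names a one-way ANOVA with contrasts against Normal. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes of a contrast were called, and counts at 1.5-fold or more are given beside them. The contrasts were PV, ET and AMM against Normal, and the 3 between diseases. Errors of differences are standard errors of the fit.

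Gene lists, 28 with 454 genes, were fixed before the data were examined, as were the groups, the tests and most alternatives. They covered autophagy and its regulation, lysosomes, signalling and inflammation, neutrophil granules and maturity, metabolism and cell death, and markers of other blood cells. Each was tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists of a contrast. Camera with a correlation estimated from the data, and fry, were alternatives. A permutation test of samples on the list median (100000 resamples, Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3) was added after the data and the other list tests were seen; it asks whether the genes of a list move between groups, and not whether they move more than other genes. Members past the threshold were counted over all genes and adjusted over the list alone.

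The genes named in the text were set by a rule fixed beforehand. It took every measured gene with an ATG symbol, the 8 largest positive and negative differences among called genes of each contrast with Normal, up to 3 called members of each other list by smallest adjusted p (or the 1 with the smallest p where none was called), and the 3 largest in each direction between diseases. Differences between diseases in ATG genes are given in the closing section by a separate rule for differences between groups.

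Alternatives tried were the title mark 4_ as a covariate, only unmarked samples, the methods' ANOVA without moderation, only the 2 groups compared, quantile normalization, centring of arrays, only genes above the median level, the mean of a gene's probe sets, every probe set tested on its own, array weights, and the means of the T lymphocyte, monocyte, eosinophil, erythroid and platelet marker lists as covariates, called marker gene means here. Where every probe set was tested, the one with the smallest p in a contrast stood for its gene. Each sample was also left out in turn. Added after the data were seen were the deposited scale, the removal of 6 arrays whose median correlation with the others was under 0.93, and the permutation test of lists. Overlaps and correlations between contrasts with Normal were set against simulated unchanged groups, and the correlations also against 100 splits of the Normal arrays into 5 and 6.

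The tests were checked on simulated data in which all groups were drawn with the same spread. The real groups differ in spread (for ATG2A the SD was 0.35 in Normal and 1.73 in PV), so these rates need not hold for them. With 11909 genes, log2 changes of 0.5, 1 and 2 were recovered for 44.1%, 86.4% and 98.5% of changed genes in PV against Normal, 58.8%, 87.9% and 100% in ET against Normal and 51.5%, 92.4% and 100% in AMM against Normal, with 4, 8 and 9 unchanged genes called. The permutation test of lists gave p under 0.05 for 4.0% of 200 unchanged lists. Figures were drawn with matplotlib 3.10.9.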

Results

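Gene expression was measured on Affymetrix arrays in neutrophils from human peripheral blood, the short-lived granule-bearing white cells that are the most abundant leukocytes of the circulation. The 66 arrays fell into 4 groups by disease status, 11 Normal, 13 PV, 24 ET and 18 that the sample labels call AMM. The series' design text counts 18 PMF samples in the place of AMM, so both names are taken here for the same group, and the labels' name is kept. PV, ET and PMF stand for polycythaemia vera, essential thrombocythaemia and primary myelofibrosis. They are chronic myeloproliferative neoplasms with, respectively, an excess of red cells, an excess of platelets and scarring of the marrow. The stated question was whether genes of the ATG family, which build the autophagosome, differ between Normal and each disease. The table held 22406 probe sets, from which 11909 genes were tested. Values are given on the log2 scale of RMA, obtained by raising 2 to the deposited values. No source states that the deposited values carry a second logarithm, so all log2 differences and folds rest on that reading of the values. Array medians lay between 5.06 and 5.22, the highest correlation of an array with another array lay between 0.957 and 0.989, and no 2 arrays held identical values. The labels do not say whether each array came from a different person, so p-values measure the spread between these samples. The number of arrays limits the precision.

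Titles of 22 samples carried the mark 4_ before a position code. They were 21 of the 24 ET samples and 1 AMM sample, and no Normal or PV sample carried it. The labels do not say what the mark means. A processing batch would be largely confounded with ET, so counts of genes, gene lists and ATG genes in comparisons with ET are also given with the mark as a covariate. Sample counts below are the samples of the first group that lay above, or below, the mean of the second.

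PV samples had more transcript of ATG7 and less of ATG14, ATG101 and ATG13 than Normal samples. ATG7, the E1-like enzyme that activates ATG12 and the ATG8 homologues for conjugation, had a mean of 7.83 ± 0.85 (SD, n = 13) in PV and 6.06 ± 0.45 (SD, n = 11) in Normal. The log2 difference was 1.77 ± 0.36 (SE), or 3.42-fold (limma, adjusted p = 0.000151), and ATG7, read by 1 probe set, was higher in 13 of 13 PV samples. ATG12, the ubiquitin-like protein that is joined to ATG5, was 0.76 ± 0.21 higher (adjusted p = 0.00767, 11 of 13 samples), and ATG2B, a lipid transfer protein, was 0.31 ± 0.08 higher (adjusted p = 0.00378, 12 of 13 samples). ATG14, which directs the class III phosphatidylinositol 3-kinase to sites of autophagosome formation, had a log2 difference of -1.07 ± 0.26 (adjusted p = 0.00175, below in 12 of 13 samples). ATG101 and ATG13, subunits of the ULK1 complex that starts autophagy, had log2 differences of -0.82 ± 0.21 (adjusted p = 0.0025) and -0.57 ± 0.11 (adjusted p = 0.000125), each below in 13 of 13 samples. ATG4B, a protease that trims ATG8 homologues, had a log2 difference of -0.42 ± 0.15 (adjusted p = 0.0334, below in 12 of 13 samples).

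In PV, 7 of the 13 measured genes with ATG symbols therefore passed the threshold, 3 higher and 4 lower. Adjusted over the list alone, 8 passed, 4 higher and 4 lower, the added gene being ATG3, an E2-like enzyme, with a log2 difference of 0.41 (adjusted p = 0.0627 over all genes, above in 9 of 13 samples). A second ATG3 probe set had 0.59 (adjusted p = 0.00393 over all probe sets). ATG3 also passed over all genes without PV 2 (0.45), PV 9 (0.48), PV 11 (0.45), PV 13 (0.46) or Normal 7 (0.47), each left out alone. The remaining log2 differences were -0.70 for ATG2A, 0.22 for ATG4A, 0.14 for ATG5, 0.44 for ATG9A and 0.19 for ATG16L1, and none of these passed. ATG2A lay at 9.23 to 10.22 in PV 1, PV 5, PV 6 and PV 7, and above the Normal mean of 12.57 in 8 of 13 PV samples. As a list the ATG genes were not set apart from other genes (median log2 difference 0.19, camera adjusted p = 0.604). ATG12 rested on the probe set chosen: the other ATG12 probe set gave 0.12, and the mean over both ended the call (0.44). Of the 3 ATG4B probe sets 2 were lower (-0.42 and -0.49) and the dimmest gave 0.03, and the call held with their mean. The ATG4B call ended without Normal 4 (-0.38), Normal 6 (-0.40), Normal 11 (-0.40), PV 3 (-0.38) or PV 12 (-0.36), each left out alone, and with marker gene means as covariates it ended too (-0.38), as did ATG14 (-0.74).

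**Figure D1:**
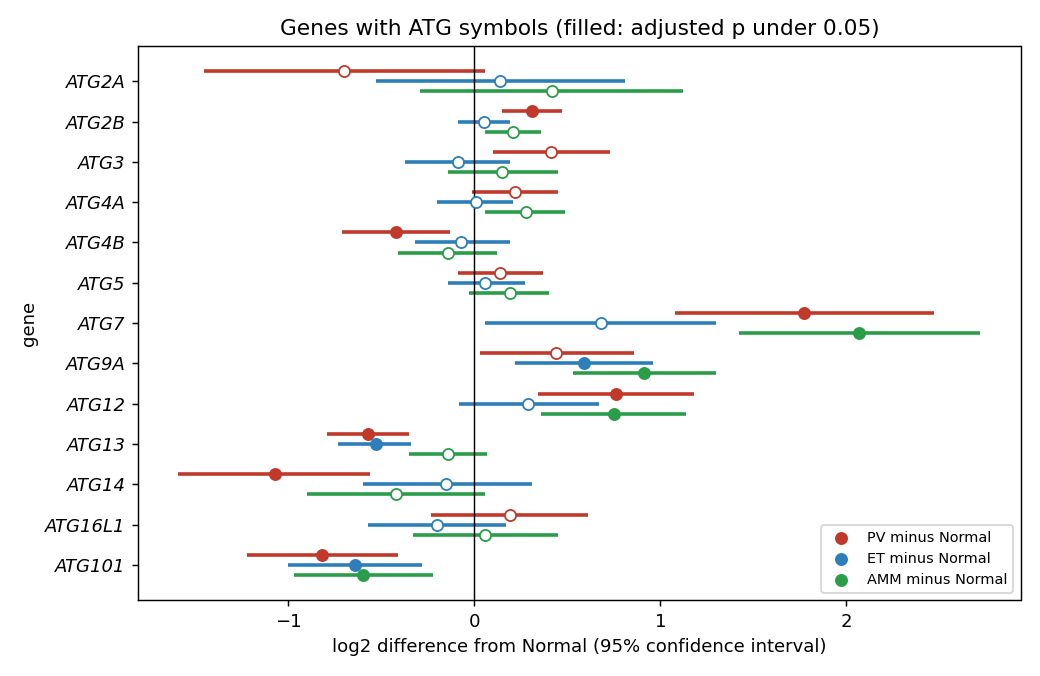
Log2 difference from Normal (x axis, log2 units, points are estimates, lines are 95% confidence intervals) of the 13 measured genes with ATG symbols (y axis) in PV, ET and AMM, with filled points for adjusted p under 0.05. ATG7 lies at 1.77 in PV, 0.68 in ET and 2.07 in AMM, and ATG13 at -0.57, -0.53 and -0.14.

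Across all genes, PV differed from Normal most in CD177, a surface glycoprotein of neutrophils, whose mean was 12.67 ± 0.86 (SD) in PV and 6.30 ± 1.28 (SD) in Normal. The log2 difference was 6.37 ± 0.82, or 82.8-fold (adjusted p = 5.5e-08), and CD177 was higher in 13 of 13 PV samples. The next largest positive differences were those of the centrosomal gene CDK5RAP2 (4.19 ± 0.53), the apoptosis inhibitor family member NAIP (3.69 ± 0.68), the haptoglobin-related gene HPR (3.25 ± 0.72), the dermatan sulphate epimerase DSE (3.18 ± 0.60), the interferon-induced IFI27 (3.13 ± 0.76), the interleukin receptor IL18R1 (3.12 ± 0.51) and PLAC8 (3.03 ± 0.50). Each was higher in 13 of 13 samples, except HPR in 12. The largest negative differences were those of the chemokine CCL4 (-2.86 ± 0.61), KLRB1 (-2.85 ± 0.55), the immunoglobulin segment IGLJ3 (-2.44 ± 0.45), GZMK (-2.29 ± 0.62), the T cell receptor zeta chain CD247 (-2.27 ± 0.45), granulysin GNLY (-2.02 ± 0.55), ITM2A (-2.01 ± 0.41) and PIK3IP1 (-1.92 ± 0.35). Each was lower in at least 12 of 13 samples. HPR and HP, and immunoglobulin segments, are near copies of other genes, and their probe sets may read more than 1 gene. In all, 2265 genes passed, 1156 higher and 1109 lower, of which 1542 differed at least 1.5-fold. The share higher was 51%, and 43.2% after quantile normalization.

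Some genes of glycolysis and hypoxia were higher in PV, where 7 of 17 measured members rose and none fell, and 10 rose adjusted over the list alone. The glucose transporter SLC2A1 was 1.00 ± 0.22 higher (11 of 13 samples), enolase ENO1 1.40 ± 0.34 higher and lactate dehydrogenase LDHA 0.96 ± 0.25 higher (12 of 13 samples each). The list's median log2 difference was 0.80 (camera adjusted p = 3.33e-05, adjusted p = 0.283 with an estimated correlation). Of the 3 genes fixed as granulocyte markers of PV, CD177 and the transcription factor NFE2 (1.76 ± 0.52, 11 of 13 samples) rose, and all 3, ALPL included, rose adjusted over the list alone (camera adjusted p = 0.00353, adjusted p = 0.283 with an estimated correlation). Among 15 target genes of STAT5 and STAT3, the transcription factors downstream of JAK2, 4 rose and 2 fell over all genes and over the list alone (median 0.41, camera adjusted p = 0.0469, adjusted p = 0.342 with an estimated correlation). Those higher included the kinase PIM1 (1.56 ± 0.26, 13 of 13 samples), BCL6 (0.84 ± 0.21, 12 of 13) and the feedback inhibitor SOCS2 (1.53 ± 0.39, 12 of 13). Of 21 lysosomal genes 4 rose and 1 fell, or 6 and 1 adjusted over the list alone (median 0.25, camera adjusted p = 0.0229, adjusted p = 0.342 with an estimated correlation), with ATP6AP1 at 0.71 ± 0.14, the galactosidase GLA at 1.12 ± 0.24 and cathepsin A, CTSA, at 0.91 ± 0.21. Of the 28 gene lists 13 were called in PV, 9 in ET and 11 in AMM against Normal, counts that chance splits of the samples also reached (in 8, 22 and 15 of 100), so single members carry the description.

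Genes made in lymphocytes were lower in PV. Of 15 T lymphocyte markers 12 fell and none rose, or 14 and none adjusted over the list alone, with a median of -1.41. CD5 had a log2 difference of -0.97 ± 0.18 (below in 13 of 13 samples), CD247 is given above, and BCL11B had -1.79 ± 0.37 (12 of 13). The camera adjusted p was 1.14e-07, and adjusted p = 0.342 with an estimated correlation. Of 11 NK cell markers 3 fell (KLRB1 and GNLY among them, and the same number adjusted over the list alone, median -0.97, camera adjusted p = 0.0195, adjusted p = 0.684 with an estimated correlation). Of 10 B lymphocyte markers 3 fell, as many as adjusted over the list alone, with PAX5 at -0.85 ± 0.15 and CD79A at -1.18 ± 0.24 (median -0.14, camera adjusted p = 0.0233, adjusted p = 0.507 with an estimated correlation). Moving with these markers, 24 of 26 cytosolic ribosomal protein genes fell and none rose, over all genes and adjusted over the list alone, with RPL30 at -0.70 ± 0.15, RPL10A at -1.91 ± 0.43 and RPS25 at -0.87 ± 0.20, each below in 12 of 13 samples. The median was -0.99 (camera adjusted p = 2.73e-12, adjusted p = 0.342 with an estimated correlation), and -0.51 with marker gene means as covariates. Of 23 genes of oxidative phosphorylation 5 fell, as many as adjusted over the list alone, among them NDUFS3 (-0.93 ± 0.21), COX4I1 (-0.57 ± 0.18) and ATP5F1A (-0.98 ± 0.30, median -0.33, camera adjusted p = 0.0139, adjusted p = 0.695 with an estimated correlation).

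The remaining called lists in PV had few members past the threshold. Of 13 specific granule genes 2 rose, HP (2.82 ± 0.60) and ARG1 (2.81 ± 0.65), each in 13 of 13 samples (median 1.56, camera adjusted p = 0.00353, adjusted p = 0.684 with an estimated correlation). PV 7 had the highest mean of both granule lists among PV arrays (13.75 for the azurophil list, where the next array had 7.56). Of 14 mature neutrophil markers 2 rose, over all genes and adjusted over the list alone, S100A12 (1.21 ± 0.30, 12 of 13 samples) and AQP9. The AQP9 call ended with any of several single samples left out, such as Normal 9 (0.43) or PV 4 (0.47). The median of this list was 0.45 (camera adjusted p = 0.0364, adjusted p = 0.703 with an estimated correlation). Of 4 basophil and mast cell markers HDC rose (1.30 ± 0.40, 13 of 13 samples), and 3 adjusted over the list alone (median 1.08, camera adjusted p = 0.0364, adjusted p = 0.641 with an estimated correlation). The mean of this list was 7.80 to 9.64 in PV 1, PV 5, PV 6 and PV 7 and 5.08 to 5.47 in the other 9 PV arrays, beside a Normal mean of 5.18. The same 4 arrays were the highest of PV in monocyte markers (9.54 to 10.71, others 7.77 to 8.90) and platelet markers (9.01 to 10.04, others 6.48 to 8.06). The erythroid list was called (median 0.76, camera adjusted p = 0.0233, adjusted p = 0.695 with an estimated correlation) with 0 of 11 members past the threshold. The azurophil list, with 0 of 8 members past the threshold, was not called (median 1.19, camera adjusted p = 0.0576), and its median was -0.70 with marker gene means as covariates.

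Among lists not called in PV, the members of early autophagy went both ways. WIPI2, a phosphoinositide-binding protein of the forming autophagosome, had a log2 difference of -0.80 ± 0.19 (below in 13 of 13 samples), and SH3GLB1 (0.93 ± 0.22) and the ULK1 partner RB1CC1 (1.15 ± 0.32) were higher in 12 of 13. In that list 4 of 16 genes rose and 1 fell (6 and 3 adjusted over the list alone). The cargo receptor NBR1 (0.82 ± 0.23, 11 of 13 samples) was the 1 of 13 ATG8 homologues and receptors to rise, and its call ended with the mean of its probe sets (0.58). Of 14 mTOR and AMPK genes 0 passed; the medians of this list and of the ATG8 homologues were 0.06 and 0.04, and both were -0.09 after quantile normalization. Of 20 inflammatory NF-kappa-B genes 1 rose and 6 fell, with the chemokines CCL4 and CXCL1 (-0.96 ± 0.30) among those lower. Immediate early genes went both ways, with DUSP2 at -1.72 ± 0.34 and KLF4 at 2.29 ± 0.59. The pro-apoptotic BBC3 had -0.73 ± 0.14 and the inhibitor of apoptosis BIRC2 had 0.75 ± 0.18, and the glutathione synthesis gene GCLM was 1.98 ± 0.32 higher, each in its direction in 13 of 13 samples. With the means of the T lymphocyte, monocyte, eosinophil, erythroid and platelet markers as covariates, the calls of HPR, HP, ARG1, SOCS2, BCL6, NFE2, ENO1, LDHA, S100A12, HDC, SH3GLB1, KLF4, KLRB1, GNLY, PIK3IP1 and COX4I1 in PV ended.

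ET samples had less transcript of ATG13 and ATG101 and more of ATG9A than Normal samples. ATG13 had a log2 difference of -0.53 ± 0.10 (adjusted p = 0.000127) and was below the Normal mean in 24 of 24 ET samples. ATG101 had -0.64 ± 0.18 (adjusted p = 0.0116, below in 21 of 24 samples), and ATG9A, the membrane-spanning protein that supplies vesicles to the forming autophagosome, was 0.59 ± 0.19 higher (adjusted p = 0.0245, 19 of 24 samples). ATG7 had a log2 difference of 0.68 ± 0.32 that did not pass (adjusted p = 0.143, above in 19 of 24 samples), with a mean of 6.74 ± 0.98 (SD, n = 24). The same 1 higher and 2 lower genes passed adjusted over the list alone. The other log2 differences were 0.29 for ATG12, -0.15 for ATG14, -0.20 for ATG16L1, 0.14 for ATG2A, 0.05 for ATG2B, -0.09 for ATG3, 0.01 for ATG4A, -0.07 for ATG4B and 0.06 for ATG5, none of them past the threshold. A second ATG5 probe set had -0.64 (adjusted p = 0.012 over all probe sets). The list as a whole was not called (median 0.01, camera adjusted p = 0.984).

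The 3 ATG calls in ET did not hold with the mark 4_ as a covariate, which leaves the ET estimate to rest largely on 3 unmarked arrays: ATG13 then had -0.40 ± 0.16, ATG101 -0.53 ± 0.30 and ATG9A 0.77 ± 0.31, so wider errors ended these calls more than smaller differences did. ATG7 was then 1.60 ± 0.49 higher without passing (adjusted p = 0.0813). Quantile normalization also ended the ATG9A call (0.52).

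**Figure D2:**
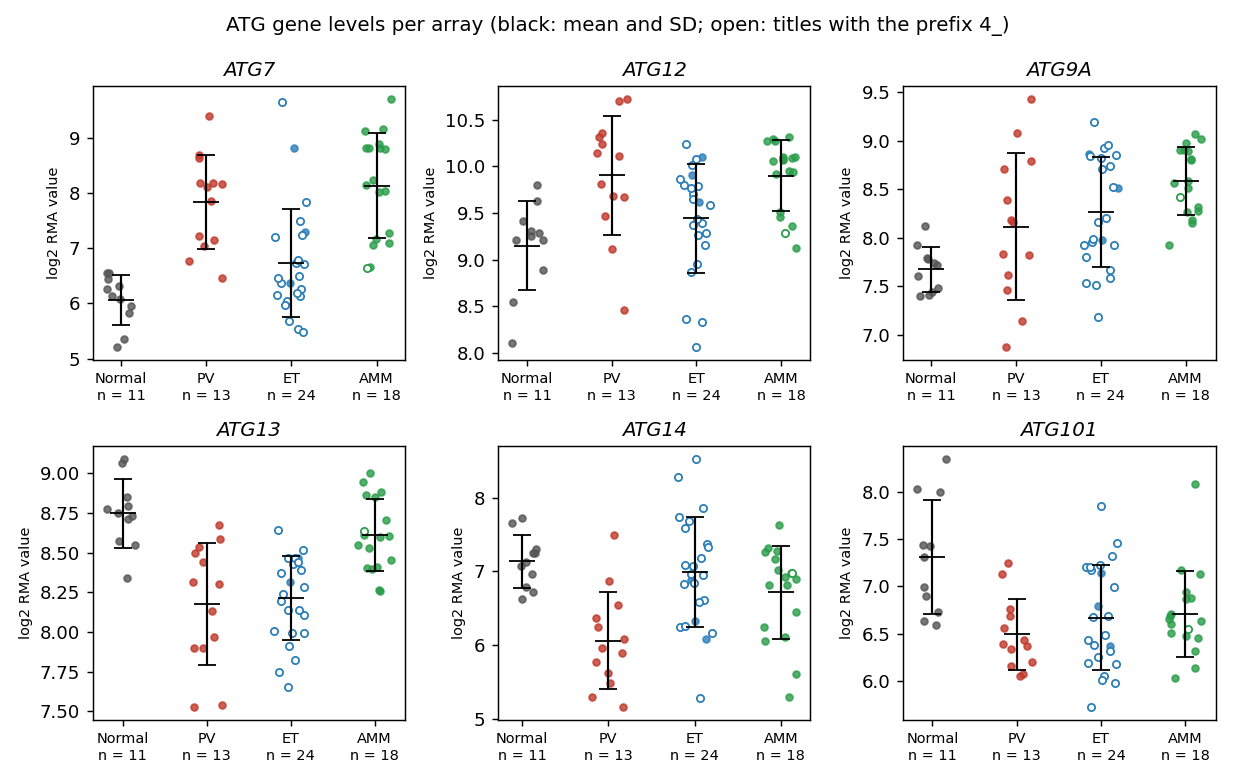
Log2 RMA value (y axis) of ATG7, ATG12, ATG9A, ATG13, ATG14 and ATG101 on each array, by group (x axis: Normal, n = 11, PV, n = 13, ET, n = 24, AMM, n = 18), with open points for arrays with the mark 4_ and black bars for mean and SD. The ATG7 means are 6.06, 7.83, 6.74 and 8.13, and the lowest AMM array, at 6.64, lies above the highest Normal array, at 6.56.

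Across all genes, ET samples had more transcript of neutrophil granule proteins and globins than Normal samples, a pattern that largely followed the mark 4_. In the unmarked arrays ET 1, ET 2 and ET 3 the erythroid list means were 7.34, 6.62 and 7.12 (Normal mean 6.91). Their azurophil list means were 5.685, 5.121 and 5.291 (Normal mean 5.24), and their specific granule means 7.95, 6.10 and 6.54 (Normal mean 6.44). Which cells these transcripts came from was not tested. The largest positive differences were those of lactoferrin LTF (2.88 ± 0.79, 20 of 24 samples), the gamma globins HBG2 (2.83 ± 0.73) and HBG1 (2.78 ± 0.72, 23 of 24 each), lipocalin LCN2 (2.66 ± 0.72, 21 of 24), the chemokine CCL2 (2.56 ± 0.82, 22 of 24), pyruvate kinase PKM (2.42 ± 0.32, 24 of 24), CD24 (2.39 ± 0.69, 23 of 24) and BPI (2.14 ± 0.69, 20 of 24). The largest negative ones were those of the translation factor EIF5A (-2.41 ± 0.46, below in 24 of 24), IGLJ3 (-1.85 ± 0.40), IMPA2 (-1.79 ± 0.48), the kinase DAPK3 (-1.75 ± 0.31), the immunoglobulin constant region IGHG3 (-1.75 ± 0.31), EGR1 (-1.74 ± 0.53), the folate receptor FOLR1 (-1.72 ± 0.26, 24 of 24) and EIF2S3 (-1.72 ± 0.35). In ET 1804 genes passed, 674 higher and 1130 lower, or 37.4% higher. Of these, 843 differed at least 1.5-fold, 412 higher and 431 lower. The share higher was 63.6% among the genes called with the mark 4_ as a covariate. HBG1 and HBG2 are near-identical genes whose probe sets may read both. With the mark as a covariate 162 genes passed, and between the 3 unmarked ET arrays and Normal 26 did; among the genes named in ET, only PKM, IGHG3 and PAX5 kept their calls with the covariate, and 0 of the named genes passed among unmarked samples. The CCL2 call also ended without Normal 5 (2.37) or Normal 8 (2.38). With marker gene means as covariates the ET calls of LTF, LCN2, CD24, BPI, HK1, CXCR1 and IFI44 ended, and that of CD24 ended with the mean of its probe sets.

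Some erythroid markers rose in ET, with 5 of 11 members higher and 6 adjusted over the list alone, among them HBG1. The median was 1.06 (camera adjusted p = 0.000122, adjusted p = 0.811 with an estimated correlation), but -0.45 with the mark as a covariate. HBB lay within 0.5 of the highest value of the tested genes, 15.36, on 58 arrays, so its differences may be compressed. Of 13 specific granule genes 4 rose, or 6 adjusted over the list alone, including LCN2 and LTF (median 1.34, camera adjusted p = 0.00295, adjusted p = 0.811 with an estimated correlation). With the mark as a covariate that median was 0.14. Of 8 azurophil granule genes BPI rose (median 1.03, camera adjusted p = 0.0227, adjusted p = 0.811 with an estimated correlation), and the median was -0.41 with the mark as a covariate. AMM 18, the 1 marked AMM array, also enters that covariate, with an erythroid mean of 11.42 and an azurophil mean of 10.30 (AMM means 9.03 and 7.6). The negative medians of both lists therefore do not describe the unmarked ET arrays alone. Of 16 platelet markers 3 rose, over all genes and adjusted over the list alone: the tetraspanin CD9 (1.45 ± 0.38, 20 of 24), the integrin chain ITGA2B (1.77 ± 0.50, 22 of 24) and MYL9 (1.49 ± 0.45, 22 of 24, list median 0.76, camera adjusted p = 0.00463, adjusted p = 0.811 with an estimated correlation). Of 17 glycolysis and hypoxia genes 4 rose, with hexokinases HK2 (1.73 ± 0.44, 22 of 24) and HK1 (0.70 ± 0.21, 21 of 24), and as many adjusted over the list alone (median 0.30, camera adjusted p = 0.0149, adjusted p = 0.811 with an estimated correlation).

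Of 10 B lymphocyte markers in ET 4 fell, or 5 adjusted over the list alone, led by PAX5 (-0.71 ± 0.13, below in 23 of 24 samples) and CD79A (-1.08 ± 0.22, 21 of 24, median -0.13, camera adjusted p = 0.0302, adjusted p = 0.811 with an estimated correlation). NK cell markers (median -0.76) and mature neutrophil markers (median -0.55, with the chemokine receptor CXCR1 at -1.31 ± 0.40) were called lower, and eosinophil markers (median 0.38, 0 of 7 members past the threshold) higher, each with a camera adjusted p of 0.0335 and with adjusted p = 0.811 with an estimated correlation. In mature neutrophil markers 3 ET arrays stood apart, with list means of 7.84 (ET 17), 8.83 (ET 21) and 9.02 (ET 6), where the next ET array had 10.19 and the lowest Normal array 10.95. With the mark as a covariate, of the 9 lists called in ET only glycolysis and hypoxia kept its call (median 0.36, camera adjusted p = 2.86e-05). Platelet (median 0.53, camera adjusted p = 0.0652), B lymphocyte (median -0.15, camera adjusted p = 0.0615) and NK cell markers (median -1.14, camera adjusted p = 0.0652) kept their direction without a call. T lymphocyte markers were not called (median -0.16, camera adjusted p = 0.528), nor were ribosomal protein genes (0 of 26 members, median -0.26, camera adjusted p = 0.0772), though the latter were called with the mark as a covariate (median -0.60, camera adjusted p = 0.000331), as was oxidative phosphorylation (median -0.43, camera adjusted p = 0.00719). In that setting 0 members of either list passed, and without the mark both had adjusted p = 0.866 with an estimated correlation. Among lists not called, the lysosomal protease cathepsin S, CTSS, had a log2 difference of -1.12 ± 0.23 (below in 24 of 24 samples), the ATG8 homologue GABARAP -0.33 ± 0.08 (23 of 24) and the NADPH oxidase subunit CYBA -1.11 ± 0.29 (22 of 24). The STAT target OSM had -1.60 ± 0.40 (21 of 24) and the chemokine CXCL1 -1.42 ± 0.27 (22 of 24). IFI44, an interferon-induced gene, was 2.09 ± 0.57 higher in 24 of 24 samples.

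AMM samples had more transcript of ATG7, ATG9A and ATG12 and less of ATG101 than Normal samples. ATG7 had a mean of 8.13 ± 0.95 (SD, n = 18), which was 2.07 ± 0.33 above Normal, or 4.20-fold (adjusted p = 1.04e-05), and was higher in 18 of 18 samples. ATG9A was 0.91 ± 0.20 higher (adjusted p = 0.000818, 18 of 18 samples) and ATG12 0.75 ± 0.20 higher (adjusted p = 0.00665, 17 of 18). ATG101 had a log2 difference of -0.60 ± 0.19 (adjusted p = 0.0278, below in 17 of 18). Adjusted over the list alone, 5 genes were higher and 1 lower, which added ATG2B (0.21, adjusted p = 0.0534 over all genes) and ATG4A (0.28, adjusted p = 0.0821, above in 18 of 18 samples). The other log2 differences, none past the threshold, were 0.42 for ATG2A, 0.15 for ATG3, -0.14 for ATG4B, 0.19 for ATG5, -0.14 for ATG13, -0.42 for ATG14 and 0.06 for ATG16L1. The list was not called (median 0.19, camera adjusted p = 0.0528). The other ATG12 probe set gave 0.12 and the mean over both ended the call (0.44). The ATG101 call ended without Normal 5 (-0.52), Normal 9 (-0.53) or Normal 11 (-0.49), and with marker gene means as covariates (-0.46).

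Across all genes, AMM samples had more transcript of granule proteins that are made in precursors of neutrophils in the marrow, and of red cell proteins. Whether these transcripts came from neutrophils or from other cells in the samples was not tested. The largest positive differences were those of LTF (3.99 ± 0.83, or 15.9-fold, adjusted p = 0.000511), carbonic anhydrase CA1 (3.94 ± 0.72), LCN2 (3.63 ± 0.75), CD177 (3.53 ± 0.77), CD24 (3.41 ± 0.72), CRISP3 (3.36 ± 0.75), OLFM4 (3.34 ± 0.79) and BPI (3.28 ± 0.72). Each was higher in 17 of 18 samples, except CD177 in 15 and BPI in 18. The largest negative differences were those of the cytokine IL1B (-2.59 ± 0.59), IGLJ3 (-2.40 ± 0.42), IMPA2 (-2.09 ± 0.51), IGHG3 (-2.05 ± 0.33), GNLY (-1.88 ± 0.51), CRIP1 (-1.88 ± 0.49), CD247 (-1.83 ± 0.42) and FGL2 (-1.81 ± 0.56). Each was lower in at least 17 of 18 samples. In all 1633 genes passed, 949 higher and 684 lower, and 1081 of them differed at least 1.5-fold. The balance of higher and lower calls moved with the scaling, from 58.1% higher to 41.8% after quantile normalization.

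Of 11 erythroid markers all 11 rose in AMM, over all genes and adjusted over the list alone, among them CA1, the haemoglobin chaperone AHSP (2.59 ± 0.59, 15 of 18 samples) and delta globin HBD (3.18 ± 0.73, 17 of 18). The median was 2.24 (camera adjusted p = 2.27e-09, adjusted p = 0.317 with an estimated correlation). Of 13 specific granule genes 9 rose, or 10 adjusted over the list alone (median 2.71, camera adjusted p = 1.17e-08, adjusted p = 0.317 with an estimated correlation). Of 8 azurophil granule genes 6 rose, or 8 adjusted over the list alone, with the defensin DEFA4 at 2.97 ± 0.82 (15 of 18) and MS4A3 at 2.56 ± 0.74 (16 of 18, median 2.36, camera adjusted p = 2.17e-05, adjusted p = 0.325 with an estimated correlation). These granule genes moved with the erythroid and other marker lists: with the marker gene means as covariates the median was 0.70 for the specific and -0.26 for the azurophil list. Of 20 genes of the type I interferon response 8 rose, or 11 adjusted over the list alone, including IFI44 (2.82 ± 0.60, 17 of 18), IFI27 (2.94 ± 0.71, 17 of 18) and the RNA sensor RIGI (1.89 ± 0.46, 18 of 18, median 1.30, camera adjusted p = 1.68e-07, adjusted p = 0.325 with an estimated correlation). Glycolysis and hypoxia genes rose in 7 of 17 cases, or 9 adjusted over the list alone, with ENO1 (1.41 ± 0.32, 17 of 18) and HK2 (1.99 ± 0.46, 16 of 18, median 0.58, camera adjusted p = 3.66e-05, adjusted p = 0.317 with an estimated correlation). Of 21 lysosomal genes 7 rose and 1 fell, or 8 and 1 adjusted over the list alone, with ATP6AP1 (0.65 ± 0.13, 18 of 18) and cathepsin D, CTSD (1.21 ± 0.28, 17 of 18, median 0.14, camera adjusted p = 0.00401, adjusted p = 0.317 with an estimated correlation). Cell cycle genes were called (median 0.22, camera adjusted p = 0.0125, adjusted p = 0.547 with an estimated correlation) with 0 of 26 members past the threshold.

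T lymphocyte markers fell in AMM for 7 of 15 members, or 8 adjusted over the list alone, including CD247, BCL11B (-1.46 ± 0.34) and CD3E (-1.68 ± 0.41), each below in 17 of 18 samples. The median was -0.80 (camera adjusted p = 3.03e-06, adjusted p = 0.325 with an estimated correlation). Of 11 NK cell markers 3 fell, or 5 adjusted over the list alone (median -1.05, camera adjusted p = 0.0011, adjusted p = 0.325 with an estimated correlation), and of 10 B lymphocyte markers 2 fell, or 3 adjusted over the list alone, with PAX5 at -0.85 ± 0.14 (18 of 18, median -0.12, camera adjusted p = 0.0065, adjusted p = 0.325 with an estimated correlation). Ribosomal protein genes moved with these markers: 9 of 26 fell and none rose, 21 fell adjusted over the list alone, and RPL10A had -1.39 ± 0.40 and RPL30 -0.45 ± 0.14. Their median was -0.67 (camera adjusted p = 1.29e-08, adjusted p = 0.325 with an estimated correlation), and -0.42 with marker gene means as covariates.

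Among lists not called in AMM, 4 of 16 members of early autophagy were higher and none lower, among them the regulator RUBCN at 1.06 ± 0.28 (16 of 18 samples), the kinase ULK1 at 0.85 ± 0.24 (17 of 18) and WIPI1 at 0.95 ± 0.28 (15 of 18). Adjusted over the list alone 6 rose and 2 fell (median 0.22, camera adjusted p = 0.119). Of 13 ATG8 homologues and receptors 2 rose and 0 fell (median 0.38, camera adjusted p = 0.0582, adjusted p = 0.325 with an estimated correlation). Permutation of samples, which does not compare a list with other genes, called both lists (adjusted p = 0.0182 and 0.00056). The kinase STK11, an activator of AMPK, was 0.63 ± 0.16 higher (16 of 18), the oxidase subunit CYBB 1.95 ± 0.43 higher (17 of 18), BIRC2 0.72 ± 0.17 higher (17 of 18) and PIM1 0.97 ± 0.24 higher (16 of 18). The chemokine CXCL1 had -1.71 ± 0.28 (below in 18 of 18) and the phosphatase DUSP2 -1.23 ± 0.32 (16 of 18). With the marker gene means as covariates the calls in AMM of LTF, LCN2, CD177, CD24, CRISP3, OLFM4, BPI, DEFA4, MS4A3, IFI44, IFI27, HK2, CTSD, GNLY, RPL30, WIPI1, STK11 and DUSP2 ended, and that of WIPI1 also ended after quantile normalization.

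**Figure D3:**
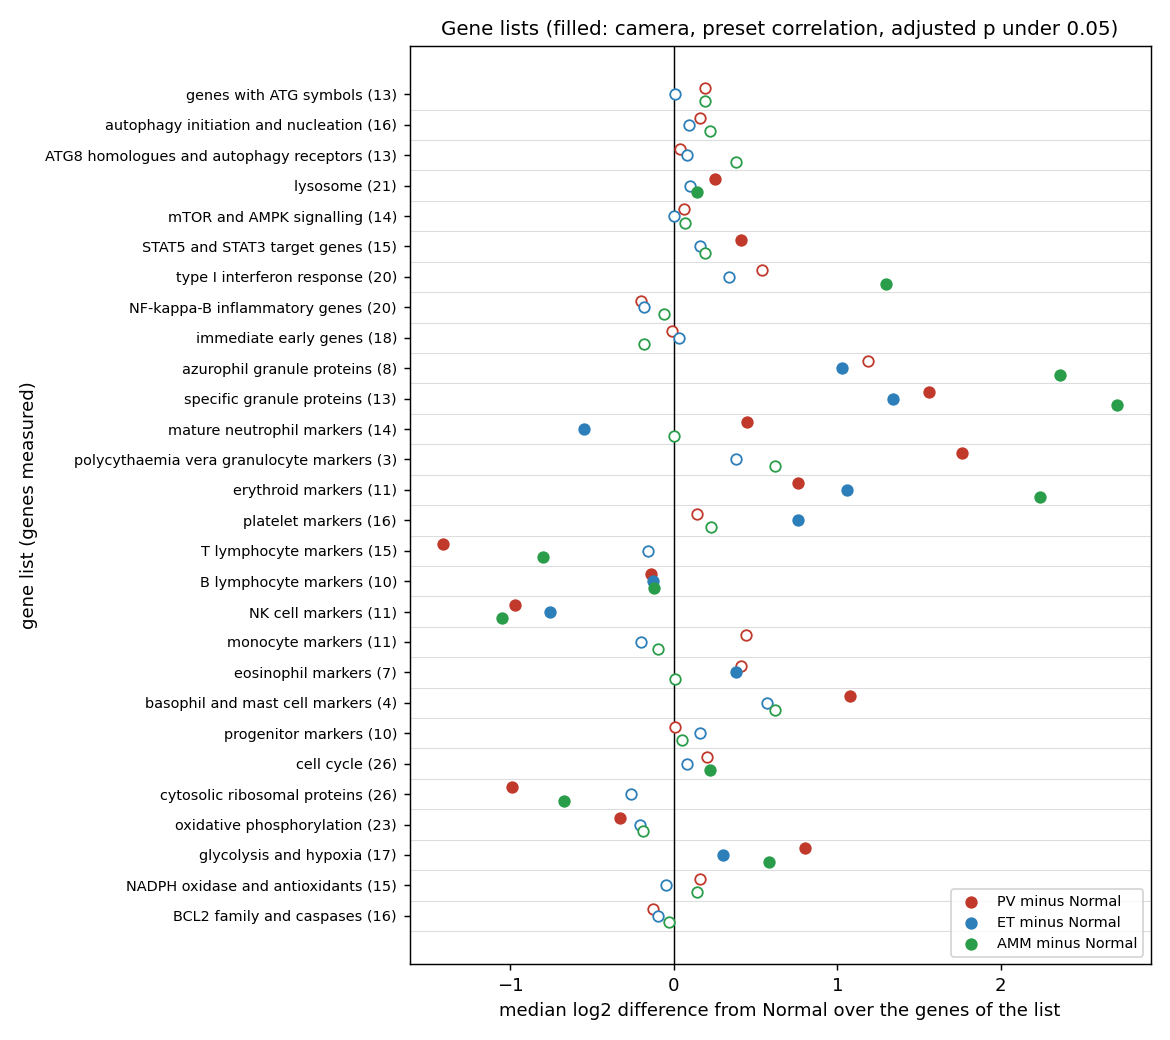
Median log2 difference from Normal (x axis, log2 units) over the measured genes of each of 28 gene lists (y axis, with the number of genes measured) in PV, ET and AMM, with filled points for a camera adjusted p under 0.05 at the preset correlation; with an estimated correlation 0 of these calls held. Specific granule genes lie at 1.56, 1.34 and 2.71, and T lymphocyte markers at -1.41, -0.16 and -0.80.

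The 3 comparisons with Normal use the same 11 Normal arrays, which by itself makes their differences alike. PV and AMM shared 654 genes higher and 559 lower, with 0 in opposite directions, where independent lists of these sizes would share 92.1 and 63.7. Simulated unchanged groups shared a median of 0, but they hold no differences to call, so this is no baseline for shared calls. How far the common Normal arrays raised the shared counts was not measured. Across genes, which are not independent replicates, the correlation of their log2 differences was 0.83 (0.55 simulated, and 0.74 with the Normal arrays split between the comparisons). The covariance was 0.179 (0.021 simulated, a difference of 0.157). PV and ET shared 360 higher and 451 lower genes, with 3 opposite (65.4 and 105.2 for independent lists), a correlation of 0.62 (0.58 simulated, 0.53 split) and a covariance of 0.112 (0.02 simulated, a difference of 0.092). ET and AMM shared 413 and 386, with 0 opposite (53.7 and 64.9), a correlation of 0.76 (0.66 simulated, 0.65 split) and a covariance of 0.118 (0.024 simulated, a difference of 0.094).

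The contrasts between diseases test whether the differences from Normal are themselves different. PV exceeded ET most in CD177 (4.54 ± 0.69), NAIP (3.47 ± 0.57) and CDK5RAP2 (3.35 ± 0.45), each in 13 of 13 PV samples. PV was lowest against ET in the transcription factors MYC (-1.95 ± 0.42, below in 12 of 13), RORA (-1.93 ± 0.35) and GATA3 (-1.93 ± 0.33, 13 of 13 each), of which the last directs T cell development. All 3 PV granulocyte markers were higher in PV (median 2.18, camera adjusted p = 0.00254, adjusted p = 0.296 with an estimated correlation), as were 10 of 14 mature neutrophil markers, or 13 adjusted over the list alone (median 0.96, camera adjusted p = 1.19e-06, adjusted p = 0.499 with an estimated correlation). ET 6, ET 17 and ET 21, low in these markers, are part of that contrast. T lymphocyte markers were lower for 12 of 15 members, or all 15 adjusted over the list alone (median -1.14, camera adjusted p = 1.42e-08, adjusted p = 0.499 with an estimated correlation), and ribosomal genes for 21 of 26, or 22 adjusted over the list alone (median -0.79, camera adjusted p = 6.83e-11, adjusted p = 0.506 with an estimated correlation). These 4 lists kept their calls with the mark as a covariate, with medians of 1.91, 0.47, -0.80 and -0.42. In all 2455 genes passed between PV and ET, 1417 higher and 1038 lower, or 57.7% higher, and 48.5% after quantile normalization. With the mark 4_ as a covariate 2 did, so batch and disease cannot be told apart for most of these genes.

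AMM exceeded ET most in the receptors LILRA5 (2.25 ± 0.36, 18 of 18 samples) and CLEC5A (1.95 ± 0.44, 14 of 18) and in CA1 (1.82 ± 0.58, 15 of 18). It was lowest against ET in GPR183 (-1.60 ± 0.35, 17 of 18), MYC (-1.53 ± 0.38, 16 of 18) and LEF1, a transcription factor of lymphocytes (-1.49 ± 0.37, 18 of 18). The ATG list was called higher in AMM than in ET, with 3 of 13 members up and none down, or 5 adjusted over the list alone (median 0.26, camera adjusted p = 0.0138, adjusted p = 0.361 with an estimated correlation). The ATG list was not called with the mark as a covariate (median 0.05, camera adjusted p = 0.717). The type I interferon list was called higher in AMM (median 0.83, camera adjusted p = 0.000159, adjusted p = 0.575 with an estimated correlation), with 2 of 20 members past the threshold and 7 adjusted over the list alone, but not by permutation of samples (adjusted p = 0.0975). T lymphocyte markers were called lower, with 5 of 15 members past it, or 8 adjusted over the list alone (median -0.70, camera adjusted p = 2.83e-06, adjusted p = 0.512 with an estimated correlation), and likewise not by permutation (adjusted p = 0.106). Both of these camera calls held with the mark as a covariate (medians 0.84 and -0.32). Ribosomal protein genes were called lower with 2 of 26 members past the threshold and 0 adjusted over the list alone (median -0.45, camera adjusted p = 3.52e-06, adjusted p = 0.575 with an estimated correlation), but not with the mark as a covariate (median -0.08, camera adjusted p = 0.171). NADPH oxidase and antioxidant genes were called higher with 3 of 15 members past it, or 7 adjusted over the list alone (median 0.30, camera adjusted p = 0.0186, adjusted p = 0.361 with an estimated correlation). That list and the ATG list were the 2 to pass by permutation (adjusted p = 0.0357 and 0.00168), and the mark as a covariate ended its camera call as well (median 0.20, camera adjusted p = 0.216). Lists of other cell types and of granules were called higher in the same contrast: erythroid (median 0.89, camera adjusted p = 0.0169), specific granule (median 1.21, camera adjusted p = 0.00329), azurophil (median 1.13, camera adjusted p = 0.0386) and mature neutrophil (median 0.56, camera adjusted p = 0.00145). Each had an adjusted p of at least 0.575 with an estimated correlation. The medians were 2.65, 2.36, 2.62 and 0.02 with the mark as a covariate, where the last was not called. AMM 18, the 1 marked AMM array, enters that covariate. It lay above the AMM mean in the first 3 of these lists (11.42, 11.07 and 10.30, beside 9.03, 8.84 and 7.6). In all 1297 genes passed, 851 higher and 446 lower. The share higher was 65.6%, and 42% after quantile normalization; with the mark as a covariate 2 genes passed, and 560 passed without 6 arrays that correlated least with the others, 5 of them ET, a setting chosen after the data were seen.

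Between AMM and PV 135 genes passed, 31 higher and 104 lower in AMM. The largest differences were those of DTX4 (1.90 ± 0.51, 15 of 18 samples), the phosphatase ACP6 (1.45 ± 0.29) and the interferon-induced exonuclease ISG20 (1.25 ± 0.28, 18 of 18 each) on the higher side, and of NAIP (-3.04 ± 0.60, 17 of 18), CDK5RAP2 (-2.90 ± 0.47, 17 of 18) and CD177 (-2.84 ± 0.73, 15 of 18) on the lower. Of the 3 PV granulocyte markers 2 were lower in AMM, or 3 adjusted over the list alone (median -2.22, camera adjusted p = 1.34e-05), and this was the 1 list call that held with an estimated correlation (adjusted p = 0.0227). The ATG list was called higher in AMM than in PV (median 0.22, camera adjusted p = 0.0291, adjusted p = 0.43 with an estimated correlation), with 1 of 13 members past the threshold, or 4 adjusted over the list alone. Of the PV arrays, PV 1, PV 5, PV 6 and PV 7 had the lowest ATG list means, all under 7.77, where the others had 7.86 to 8.30. Erythroid markers (median 1.38, camera adjusted p = 1.64e-06, adjusted p = 0.43 with an estimated correlation) were called higher and monocyte markers (median -0.36, camera adjusted p = 0.000699, adjusted p = 0.466 with an estimated correlation) lower in AMM as well. Neither passed by permutation of samples (adjusted p = 0.123 and 0.544). The monocyte list means were 9.54 to 10.71 in PV 1, PV 5, PV 6 and PV 7 and 7.77 to 8.90 in the other PV arrays, beside an AMM mean of 8.28. The count of genes was 68 without PV 1, 84 without PV 6 and 206 without AMM 1, 30 in a fit of the 2 groups alone, and 2 with the marker gene means as covariates.

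T lymphocyte markers and ribosomal protein genes also varied together among arrays of 1 group. Between the mean of the 15 T lymphocyte markers and that of the 26 ribosomal genes, Pearson's r was 0.91 in Normal (n = 11, permutation p = 7e-05), 0.75 in PV (n = 13, p = 0.0035 by permutation), 0.75 in ET (n = 24, permutation p = 2e-05) and 0.84 in AMM (n = 18, permutation p = 2e-05). Spearman's rho was 0.90, 0.74, 0.78 and 0.84 (permutation p = 0.00037, 0.005, 3e-05 and 1e-05). The 5 relations of this family include the 21 marked ET arrays alone, where r was 0.71 (permutation p = 0.00026) and rho 0.75 (permutation p = 0.00015). The Benjamini-Hochberg adjusted values for r were 0.00012, 0.0035, 5e-05, 5e-05 and 0.00032, and for rho 0.00046, 0.005, 7.5e-05, 5e-05 and 0.00025. Without the 2 samples farthest from the median of the T lymphocyte mean, r was 0.86, 0.72, 0.84, 0.78 and 0.79. All tests were two-sided. The 3 unmarked ET arrays are too few for a value.

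**Figure D4:**
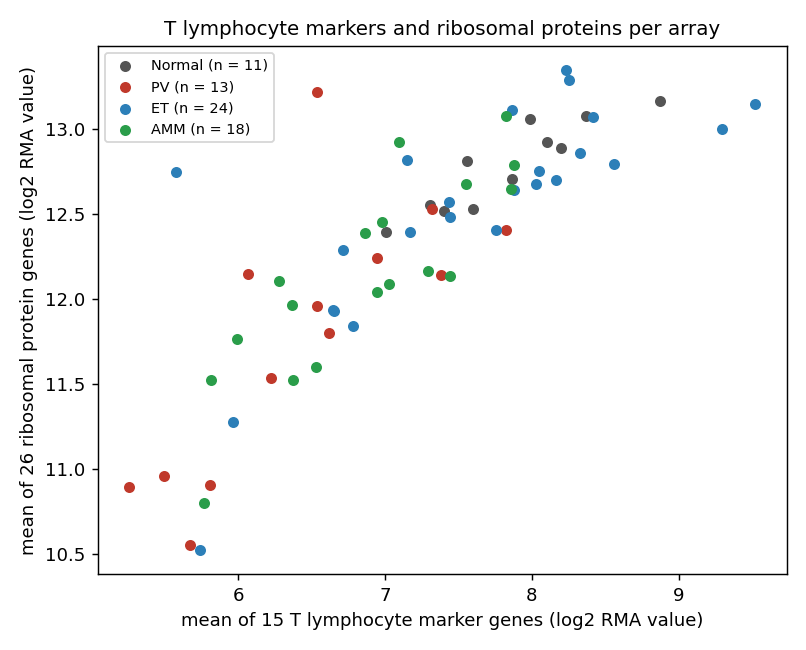
Mean log2 RMA value of 26 ribosomal protein genes (y axis) against that of 15 T lymphocyte marker genes (x axis), with 1 point per array, coloured by group (Normal, n = 11, PV, n = 13, ET, n = 24, AMM, n = 18). The group means of the T lymphocyte markers are 7.84, 6.44, 7.57 and 6.88, and those of the ribosomal genes 12.78, 11.79, 12.53 and 12.15.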

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

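The splits of samples behind the counts of genes were tests chosen only after those counts were seen, and the joint reading of 2 covariate settings for ribosomal genes was decided after their values were seen. The other tests of this part were set down before the result they measure.

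Differences between diseases in genes with ATG symbols drew attention because the contrast between 2 diseases itself passed the test. Between PV and ET, ATG7 was 1.10 higher in PV (adjusted p = 0.00617), ATG3 0.51 higher (adjusted p = 0.00559) and ATG2B 0.26 higher (adjusted p = 0.00411), and ATG14 had a log2 difference of -0.93 (adjusted p = 0.00163) and ATG4B of -0.36 (adjusted p = 0.031). Between AMM and ET, ATG7 was 1.40 higher in AMM (adjusted p = 0.000634), ATG13 0.39 higher (adjusted p = 0.00219) and ATG4A 0.27 higher (adjusted p = 0.039). Between AMM and PV, ATG13 was 0.43 higher in AMM (adjusted p = 0.0129). The contrasts with ET are nearly those between arrays with and without the mark 4_, so batch and disease cannot be told apart in them. With the mark as a covariate none of these 8 differences passed. Between PV and ET they were then 0.18 ± 0.48 for ATG7 (error 0.30 before), 0.11 ± 0.22 for ATG3 (0.14), 0.08 ± 0.11 for ATG2B (0.07), -0.45 ± 0.36 for ATG14 (0.22) and -0.31 ± 0.21 for ATG4B (0.12). Between AMM and ET they were 0.53 ± 0.45 for ATG7 (0.27 before), 0.27 ± 0.15 for ATG13 (0.09) and 0.22 ± 0.15 for ATG4A (0.09). ATG4B and ATG4A kept most of their size, so wider errors ended these calls, while ATG7, ATG3 and ATG2B shrank to under 40% of theirs. The contrast of AMM with PV holds 1 marked array, and its ATG13 difference was 0.44 with the mark as a covariate (adjusted p = 0.0122). In PV 1, PV 5, PV 6 and PV 7, the PV arrays highest in monocyte and platelet markers, ATG13 lay at 7.52 to 7.97. The other PV arrays had 7.90 (PV 11) to 8.68 (PV 4), beside an AMM mean of 8.61. How much of the difference rests on the low arrays was not tested. The contrast called 135 genes, but 30 in a fit of the 2 groups alone and 2 with marker gene means as covariates. The ATG13 value in those fits is not given here.

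Probe sets without a gene name in the annotation used here also differed between groups, and no gene-level result uses them. Of 2866 such probe sets, 501 passed the threshold between PV and Normal (236 higher, 265 lower), 464 between ET and Normal (177 higher, 287 lower) and 360 between AMM and Normal (182 higher, 178 lower). Those are 17.5%, 16.2% and 12.6%, beside 18%, 14.8% and 12.6% of probe sets with a gene name. The rule used here for single far samples covers groups of 4 to 10 samples, so it was not applied to these 4 larger groups.

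ATG7 was higher in PV and AMM than in Normal. A smaller share of lymphocytes among the cells was tested with the mean of the T lymphocyte markers as a covariate, which left the log2 difference at 1.60 ± 0.40 in PV (adjusted p = 0.00406) and 1.96 ± 0.36 in AMM (adjusted p = 0.000179), from 1.77 and 2.07. A larger share of cells rich in granule transcripts was tested with the mean of the specific granule genes, which left 1.88 ± 0.37 in PV (adjusted p = 0.000108) and 2.26 ± 0.37 in AMM (adjusted p = 2.23e-05). Both are therefore argued against as the whole cause. Shares of monocytes, erythroid cells or platelets were not tested singly for ATG7 and stay open. Among what stays open are the 1 probe set that stands for ATG7, treatment, which is unknown, and RNA quality, which was not assessed. A difference that belongs to the diseases, which may or may not concern autophagy, also stays open. None of these was tested.

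Ribosomal protein genes were lower in PV and AMM than in Normal, together with T lymphocyte markers. With the T lymphocyte mean as a covariate their median log2 difference was -0.20 in PV (95% bootstrap interval -0.57 to 0.18, before -0.99) and -0.09 in AMM (-0.31 to 0.15, before -0.67). With 5 marker list means as covariates it was -0.51 and -0.42, so these settings part, and a smaller share of lymphocytes cannot be told apart from a change within neutrophils. Lower values of all bright genes in PV arrays are argued against, since the ribosomal median lay at percentile 0 of 10000 random lists of genes matched on level, whose medians lay between -0.13 and 0.26 (95% range). A difference between the diseases stays among the open explanations.

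Differences between ET and Normal coincide with the mark 4_, carried by 21 of 24 ET arrays and by no Normal array. If the mark were the whole cause, genes called between marked ET and part of the Normal arrays would show no difference between the 3 unmarked ET arrays and the other Normal arrays. The slope of the second set of differences on the first was 0.57 (0.45 to 0.78 over 100 splits of the Normal arrays, with a median of 490 genes). The same 3 unmarked ET arrays entered every split, so this range leaves out the spread among ET arrays. The test therefore cannot decide whether the mark is the whole cause. The slope also pools genes, and called lists went both ways with the mark as a covariate. The erythroid median went from 1.06 to -0.45 and the azurophil median from 1.03 to -0.41. The covariate is 1 effect fitted over ET and AMM, so AMM 18, the 1 marked AMM array, also enters these medians. Its erythroid mean was 11.42 (AMM mean 9.03) and its azurophil mean 10.30 (AMM mean 7.6). The 3 unmarked ET arrays themselves had erythroid means of 6.62 to 7.34 (Normal mean 6.91) and azurophil means of 5.12 to 5.69 (Normal mean 5.24). The platelet median went from 0.76 to 0.53, and that of glycolysis and hypoxia from 0.30 to 0.36. Part or all of the differences may come with the mark, and with 3 unmarked arrays batch and disease cannot be told apart for single genes.

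Other splits of the samples, 100 per comparison with the real one included, show how often a random division calls as many. For the counts of genes, none of the other splits did so in any comparison but AMM against PV. The real counts and the highest of the other splits were 2265 and 35 for PV, 1804 and 134 for ET and 1633 and 2 for AMM against Normal. They were 2455 and 848 for PV against ET, and 1297 and 402 for AMM against ET. Each of these counts was reached by 1 split, the real one. In comparisons with ET the splits also mix arrays with and without the mark 4_, so they do not part disease from the mark. Between AMM and PV 2 of 100 splits gave as many genes, with 135 for the real split and 138 for another. For genes with ATG symbols the splits tell nothing either way: 7, 3 and 4 passed in PV, ET and AMM against Normal, 0 was the highest other and 1 split each reached as many, but other splits called so few of the 11909 genes that none of 13 fixed beforehand would be due among them. For the counts of gene lists chance cannot be excluded in any comparison. As many lists were called in 8, 22, 15, 87, 7 and 14 of 100 splits for PV, ET and AMM against Normal, PV against ET, AMM against ET and AMM against PV. The real counts were 13, 9, 11, 4, 12 and 13, and the highest others 16, 15, 13, 17, 14 and 15.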

How the results depend on the processing

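The deposited scale, the removal of 6 arrays and the permutation of samples for lists were tests chosen only after the data were seen. No paired analysis was possible because the labels link no samples to each other. RNA quality was not assessed, since the table holds 0 control probe sets, and signal over background is unknown.

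Most counts kept within 1.5 times their value. For PV against Normal the count of genes ran from 1589 with marker gene means as covariates to 3081 with array weights, and was 1918 to 2341 with 1 sample left out. For ET against Normal it was 1393 to 1915 with 1 sample left out, but 162 with the title mark as a covariate and 26 with only unmarked samples, which leave 3 ET arrays. For AMM against Normal it was 1243 to 1770 with 1 sample left out and 2771 with array weights. The cause was not tested where no construction shows it.

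Between diseases the counts moved more. PV against ET gave 2 genes with the mark as a covariate, 1 with only unmarked samples and 513 with marker gene means. AMM against ET gave 2 and 1 in the first 2 of these, 775 with marker gene means and 560 without the 6 arrays. It gave 814 with only genes above the median level (fewer genes tested). With every probe set tested it gave 2036, where the probe set of smallest p stood for each gene. AMM against PV gave 30 with only the 2 groups, 206 with array weights, 2 with marker gene means and 233 without the 6 arrays. With 1 sample left out it gave 68 (without PV 1) to 206 (without AMM 1), and 84 without PV 6.

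The count of ATG genes was 5 to 8 in PV and 3 to 6 in AMM over all alternatives. In ET it was 0 with the mark as a covariate, 0 with only unmarked samples and 5 with marker gene means, where ATG7 (0.99) and ATG12 (0.50) were added.

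Counts of gene lists depended most on the test. With an estimated correlation they were 0, 0 and 0 for PV, ET and AMM against Normal, 0 for PV against ET, 0 for AMM against ET and 1 for AMM against PV. With fry they were 9, 2, 13, 8, 10 and 1, and by permutation of samples 11, 0, 13, 5, 2 and 2, in the same order. With the mark as a covariate 3 lists were called in ET against Normal, 8 in PV against ET and 7 in AMM against ET, and with only unmarked samples 8 and 7 in the last 2. With marker gene means, which leave 23 lists, there were 3 in PV, 5 in ET, 6 in AMM against ET and 4 in AMM against PV. The ATG list was called by permutation in PV (adjusted p = 0.0212) and AMM (adjusted p = 0.0182), and not in ET (adjusted p = 0.96). Between diseases it was called in AMM against ET (adjusted p = 0.00168) and AMM against PV (adjusted p = 0.0265), and not in PV against ET (adjusted p = 0.459).

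Some differences changed sign, and the cause was not tested. In PV, ATG5 had -0.012 after quantile normalization and -0.065 with the mean of probe sets. In ET, ATG3 had 0.304 with the mark as a covariate, 0.369 with only unmarked samples, 0.02 with the mean of probe sets and 0.132 with every probe set tested. ATG4A in ET had -0.009 with array weights, -0.01 with marker gene means, 0 on the deposited scale and -0.029 to 0.031 with 1 sample left out. ATG5 in ET had -0.209 with the mean of probe sets and -0.635 with every probe set tested. In the latter setting another probe set, of smaller p, stood for ATG5, and likewise for ATG3. In ET the NK cell marker NCR1 had 0.133 with the mark as a covariate and 0.103 with only unmarked samples, and SMPD3 had -0.078 and MCM7 0.062 with only unmarked samples. In AMM, ATG16L1 had -0.025 with array weights and, with 1 sample left out, -0.005 to 0.132, and with marker gene means BCL2L1 had -0.031 (from 1.09) and RRM2 -0.29 (from 1.12), of which only BCL2L1 had passed.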

Other observations

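The alternative that leaves out 6 arrays, which is named here, was chosen only after the result was seen. Those arrays, 1 PV and 5 ET, had a median correlation with the others under 0.93, where the range over all arrays was 0.899 to 0.97. Without them 2630 genes passed in PV, 1882 in ET and 2064 in AMM against Normal.

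Some further lists were not called against Normal. Type I interferon genes had medians of 0.54 in PV and 0.34 in ET (camera adjusted p = 0.0732 and 0.0556), monocyte markers 0.44, -0.20 and -0.10 in PV, ET and AMM (camera adjusted p = 0.22, 0.678 and 0.474), and progenitor markers 0.01, 0.16 and 0.05 (camera adjusted p = 0.546, 0.136 and 0.235). Genes of the BCL2 family and caspases had medians of -0.13, -0.10 and -0.03 (camera adjusted p = 0.961, 0.653 and 0.805). In AMM their mean was 0.01 and the test pointed up while the median was negative.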
